A study of Mus musculus with 4 samples.

How the data were processed

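Total RNA from the small intestine of C57BL/6 mice was measured on 4 single-colour Affymetrix expression arrays, after labelling with biotin. Per the labels, 2 arrays came from wild-type mice, with sample titles ending in XX and XY, and 2 from mice carrying a CFLARs transgene (CFLARs Tg), with titles ending in XCFX and XCFY. CFLARs is the short form of the protein encoded by Cflar, a regulator of caspase-8 that is also called cFLIP. The XX and XCFX arrays are called the XX-type pair here and the XY and XCFY arrays the XY-type pair, which is a reading of the title notation. Wild-type replicate 1 is the XX array, wild-type replicate 2 the XY array, CFLARs Tg replicate 1 the XCFX array and CFLARs Tg replicate 2 the XCFY array. These numbers only name arrays. The labels do not say how many animals stand behind each array. The sex-linked genes differed between the 2 arrays of each genotype (see Results), so these arrays are not repeats of 1 sample. The p-values measure the spread between these samples, which also holds the difference between the sex types and may be technical in part. Between the CFLARs Tg arrays it would also hold any difference in the copy number of the transgene, which the labels do not give. The age of the mice and the stretch of the small intestine were not given in the sources used here.

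The values deposited by the authors are log2 expression values, 1 per probe set and array, for 28856 probe sets. The summarisation, background correction and normalization behind them were not given in the sources used here. Over all probe sets the deposited log2 values ran from 4.33 to 14.55, and the array medians lay between 8.31 and 8.33, so the arrays shared nearly one distribution before any step taken here. The table held 0 missing values. The log2 values were used as deposited, with no further transformation in the main setting.

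Gene names came from the platform annotation supplied for the probe sets. A single gene symbol was given for 21789 probe sets and several symbols for 1621, and 5446 probe sets were not listed or had no symbol. Only probe sets with 1 symbol were named. The gene table of mouse assembly GRCm38.p6 held the gene identifiers of 21698 of these probe sets, which changed 0 symbols. The table served for names and for the chromosome of a gene only, and no coordinates are printed. The 21789 probe sets stood for 19938 genes, of which 999 had more than 1 probe set. The probe set with the highest mean over the 4 arrays represented each gene. Among the 148 genes past the threshold with more than 1 probe set, 1 had another probe set with an unadjusted p under 0.05 in the opposite direction.

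The 30% of genes with the lowest mean over the 4 arrays, those under a mean log2 value of 7.48, were left out, and 13956 genes were fitted. CFLARs Tg was compared with wild-type (2 arrays against 2) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without covariates, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 2.64 degrees of freedom. Differences are given as CFLARs Tg minus wild-type on the log2 scale with the moderated standard error (SE), and group values as the mean ± SD of 2 arrays. Because probe sets carry background signal, a difference that reaches down to that level understates the change in RNA. The Y-linked genes in XX-type arrays and Xist in XY-type arrays gave readings of 5.13 to 6.78, which served as a scale for background. The wild-type means of H2-M2, Cxcl2, Gsdmc4, Stfa2, Tnip3 and Cxcr2 and the CFLARs Tg means of Sdr16c5 and Pnliprp1 lay within this range, as did the XCFY readings of Alb, Ahsg and Abcb11, so the sizes of their differences are lower bounds.

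For 30 gene lists (494 entries, of which 437 had a probe set of their own on the array and 363 were fitted), the shift of the list was tested with limma's camera at a preset inter-gene correlation of 0.01. The 29 lists with at least 3 fitted members were tested and adjusted together, and again with a correlation estimated per list. Each list's calls were also counted after adjustment over the list alone. The difference of each pair of arrays (XCFX minus XX, and XCFY minus XY) has no replicate, so it is given as a value without a test, and a list's median difference is placed among 10000 random lists of the same size matched on mean expression. The difference between the pairs leaves no residual degrees of freedom and has no test either. The number of arrays limits the precision throughout.

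The lists, the groups, the tests, the other settings and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls past the threshold with both CFLARs Tg arrays beyond both wild-type arrays, up to 4 fitted members of each list with the largest mean difference in either direction, the 10 largest rises and 10 largest falls in each pair, and the label check genes, leaving out predicted genes without a standard name. Genes outside the rule are said to be chosen after their values were seen.

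The fit was first tested on simulated arrays with the means and spread of the 13956 genes, 2 arrays against 2, in which 200 genes were changed. It recovered 34.3% of 67 genes changed by a log2 difference of 0.5, 82.1% of 67 genes changed by 1 and 93.9% of 66 genes changed by 2, with 2 false calls among 142. The simulated genes were independent and had the same spread in both genotypes. In the data the log2 differences had an SD of 0.231 between the CFLARs Tg arrays and 0.125 between the wild-type arrays. These rates may therefore not hold for the real fit. Alternatives covered the filter, the normalization, the choice of probe set, sex type as a block, a variance trend, a minimum effect (limma's treat against a log2 difference of 0.5), all probe sets, leaving out each array in turn, and, for the lists, an estimated correlation and ranks. The planned offsets added before taking logs were not run, since the values were already on the log2 scale. A bootstrap over genes used 10000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.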

Results

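The expression of 13956 genes was compared between the small intestine of CFLARs Tg mice and that of wild-type mice. Each genotype was represented by 2 arrays, 1 titled with an XX-type and 1 with an XY-type notation. The series title places the mice in a study of necroptosis of intestinal epithelial cells and of inflammation of the ileum, and the comparison asks how the intestinal transcriptome differs between the genotypes. The 4 arrays had lower quartiles of 6.87 to 6.94 and upper quartiles of 9.80 to 9.82 over all probe sets. No pair of arrays was a duplicate: at most 33 of 28856 probe sets had the same value on any pair of arrays. The wild-type arrays differed least, with an SD of 0.125 for the log2 differences of autosomal genes, against 0.231 for the CFLARs Tg arrays. Between genotypes this SD was 0.352 in the XX-type pair and 0.463 in the XY-type pair.

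Cflar itself read 9.31 ± 0.04 in wild-type and 9.40 ± 0.13 in CFLARs Tg (log2, n = 2), a difference of 0.08 (SE 0.08, limma adjusted p = 0.498). Its 3 probe sets differed by -0.05, 0.08 and 0.08 between the genotypes. Which part of the transgene these probe sets match is not known here, so Cflar does not check the genotype labels. The sex-linked genes followed the title notation. Xist, the RNA that coats the inactive X chromosome, read 12.9 in the XX and XCFX arrays, and 6.78 and 6.62 in the XY and XCFY arrays. The Y-linked genes Kdm5d, Uty and Eif2s3y lay between 5.13 and 6.12 in the XX-type arrays and between 9.08 and 10.35 in the XY-type arrays. Ddx3y had no probe set with a single gene symbol and was not analysed here.

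In CFLARs Tg intestine, 1178 genes rose and 1517 fell relative to wild-type (limma, adjusted p under 0.05), which is 19.3% of the genes fitted. The largest rises were those of the antimicrobial lectins Reg3g and Reg3b. Reg3g rose from 7.46 ± 0.18 to 13.06 ± 0.08, a 48.5-fold difference (log2 difference 5.60, SE 0.10, adjusted p = 0.000609). Reg3b rose from 8.31 ± 0.23 to 13.44 ± 0.12, a 35.1-fold difference (SE 0.13 on the log2 scale, adjusted p = 0.000957). H2-M2, a nonclassical class I histocompatibility gene, rose at least 21.4-fold, and the neutrophil-attracting chemokine gene Cxcl2 rose at least 21.1-fold, since their wild-type means lay within the range of background. Saa3, which encodes an acute-phase protein, rose 19.6-fold, and the phospholipase gene Pla2g4c rose 18.7-fold. Cxcl9, an interferon-gamma-inducible chemokine gene, rose 12.8-fold, inducible nitric oxide synthase (Nos2) 11.6-fold, the gasdermin gene Gsdmc2 11.3-fold and the epithelial oxidase gene Duox2 11.0-fold. The adjusted p of these genes ran from 0.000609 for Reg3g and Nos2 to 0.00899 for Cxcl2.

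The largest fall was that of Mme. This gene, which encodes the peptidase neprilysin, fell from 11.82 ± 0.02 to 8.15 ± 1.78, a 12.7-fold difference (SE 0.83 on the log2 scale, adjusted p = 0.0459). The gluconeogenic genes Pck1 fell by 3.33 (SE 0.29) and G6pc fell by 3.24 (SE 0.74) on the log2 scale, and Slc2a2, the basolateral glucose transporter gene, fell 6.85-fold. Abcb11, a bile salt transporter gene, fell at least 9.12-fold, Sectm1b 8.50-fold, and Lrat, which esterifies retinol, 6.98-fold. Cym, the gene of the milk-clotting enzyme chymosin, fell 7.13-fold, Smcp, a gene of the sperm mitochondrial capsule, 5.51-fold and Sdr16c5, a retinol dehydrogenase gene, at least 4.94-fold, to a mean of 6.72, within the range of background. The calls of Mme and G6pc were lost without a filter (adjusted p = 0.0507 and 0.0525). Against a minimum log2 difference of 0.5, 3 of the 10 falls passed, Pck1, Cym and Lrat, and the other 7 did not (adjusted p from 0.165 for Abcb11 to 0.466 for G6pc). The 2 CFLARs Tg arrays differed more from each other in most of these genes than in the genes that rose: Mme read 9.41 in the XCFX array and 6.89 in the XCFY array. The fold of 6 falls moved by over 1.5 times when a CFLARs Tg array was left out. Without replicate 1 and without replicate 2, in this order, the log2 differences were -4.93 and -2.41 for Mme, -4.37 and -2.11 for G6pc, -3.89 and -2.49 for Abcb11, -3.89 and -2.28 for Sectm1b, -3.38 and -2.17 for Slc2a2, and -3.11 and -1.81 for Smcp.

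**Figure D1:**
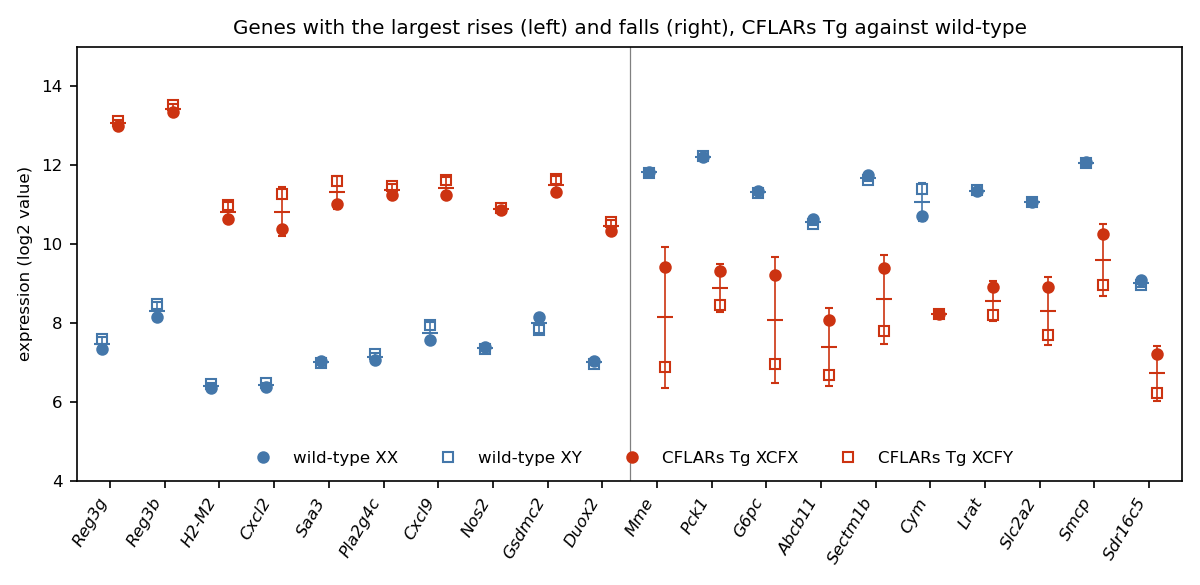
Expression (log2 value, vertical axis) on each of the 4 arrays of the 10 genes with the largest rise and the 10 with the largest fall, with points for arrays and bars for the mean ± SD of 2 arrays per genotype. Reg3g stood at 7.46 in wild-type and 13.06 in CFLARs Tg, and the CFLARs Tg arrays lay closer together in most rises than in most falls, of which Cym was an exception.

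The number of calls rested on the small spread between the wild-type arrays. Without wild-type replicate 1, when the spread came from the CFLARs Tg arrays alone, 42 genes passed, and without wild-type replicate 2, 40 genes passed, of which 37 and 39 were among the 2695. Of the 10 largest rises, 9 passed in each case, with Cxcl2 lost (adjusted p = 0.0577 and 0.0529), and of the 10 largest falls only Cym passed (adjusted p = 0.00939 and 0.0147). Without CFLARs Tg replicate 1 and replicate 2 the counts were 6559 and 4526. Against a minimum log2 difference of 0.5 (limma's treat), 63 genes passed, 53 of them higher and 10 lower in CFLARs Tg.

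Of the 29 gene lists tested, 11 shifted up and 4 shifted down in CFLARs Tg (camera, preset correlation, adjusted p under 0.05). With a correlation estimated per list, 0 of the 29 lists passed, and unadjusted p-values under 0.05 were found for 3 of them, the cytokine, the immediate early and the antimicrobial lists (0.0187, 0.0311 and 0.0389). The largest upward medians were those of neutrophil genes (1.51), inflammatory cytokines and chemokines (1.50) and antimicrobial and epithelial defence genes (1.43), and the largest downward median was that of liver genes (-1.11, or -0.57 without CFLARs Tg replicate 2).

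**Figure D2:**
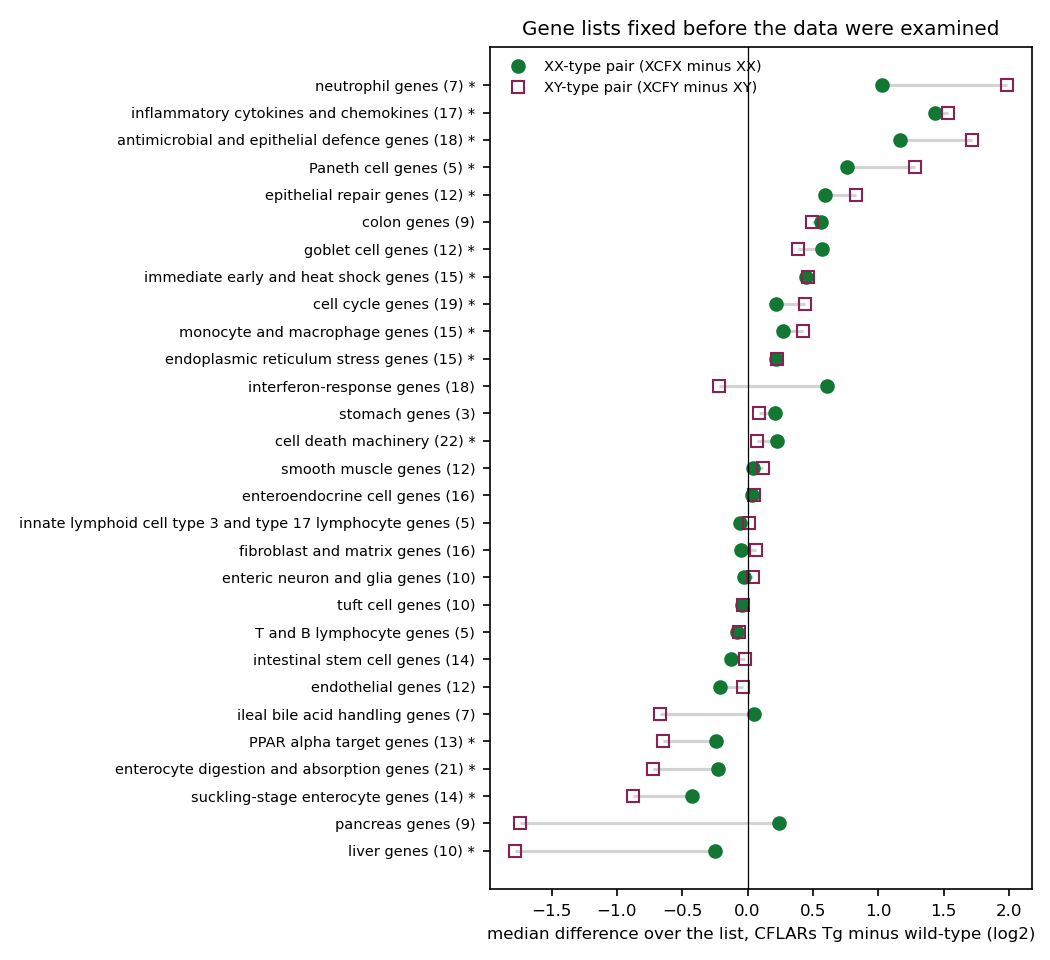
Median difference from wild-type (log2, horizontal axis) over the fitted members of each gene list, whose number is in brackets, in the XX-type pair (circles) and the XY-type pair (squares); a star marks lists past the camera threshold with the preset correlation. Neutrophil, cytokine and antimicrobial lists lay to the right in both pairs, while interferon-response and pancreas lists lay on opposite sides of 0.

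Antimicrobial and epithelial defence genes rose together. Of 18 fitted members, 13 rose and 0 fell (16 rose when adjusted over the list alone), with a median of 1.43 (camera adjusted p = 3.31e-10; adjusted p = 0.376 with an estimated correlation). Besides Reg3g and Reg3b, Saa3 rose from 7.02 ± 0.03 to 11.31 ± 0.42 and Nos2 from 7.37 ± 0.05 to 10.90 ± 0.04. Without either wild-type array, Reg3b, Reg3g, Saa3, Nos2 and Duox2 still passed, and the other 8 members did not. With the lowest 50% of genes left out, the list's median was 0.75 (camera adjusted p = 2.31e-08).

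Inflammatory cytokines and chemokines rose as well: 13 of 17 fitted members rose and 0 fell (14 rose and 1 fell when adjusted over the list alone), with a median of 1.50 (camera adjusted p = 3.31e-10; adjusted p = 0.376 with an estimated correlation). Without a filter on low values, when all 25 members were fitted, the list's median was 1.02. Ccl20, which attracts lymphocytes and dendritic cells that carry Ccr6, rose from 8.46 ± 0.06 to 11.55 ± 0.03. Cxcl10 rose by 2.87 (SE 0.12, adjusted p = 0.00391) and Ccl3 by 2.78 (SE 0.57, adjusted p = 0.0378). Without wild-type replicate 1, 5 members still passed, and without wild-type replicate 2, 4 members did, Ccl20 and Cxcl10 in both cases and Ccl3 in neither.

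Markers of neutrophils were higher among the 7 of 14 members that passed the filter on low values. Of 7 fitted neutrophil genes 5 rose and 0 fell (5 when adjusted over the list alone), with a median of 1.51 (camera adjusted p = 0.000531; adjusted p = 0.676 with an estimated correlation). Cxcr2, the receptor for Cxcl2, rose from 6.71 ± 0.17 to 9.14 ± 0.86, Il1r2 from 7.19 ± 0.28 to 9.34 ± 0.85, Ly6g from 6.93 ± 0.13 to 8.74 ± 0.57 and Csf3r from 7.30 ± 0.16 to 8.81 ± 0.52. The list of monocyte and macrophage genes shifted up with a median of 0.34 (camera adjusted p = 0.00201, or 0.676 with an estimated correlation). However, 0 of its 15 members passed the test of single genes, over all genes or over the list alone. An unadjusted p under 0.05 (limma) was found for 6, a share like that of all fitted genes (5457 of 13956). Itgam differed by 1.22 (SE 0.34), Cd14 by 1.11, Lyz2 by 0.99 and Fcgr3 by 0.91, and these 4 genes passed with sex type as a block (adjusted p from 0.0191 to 0.0305). Without CFLARs Tg replicate 2 the list's median was 0.23. Without wild-type replicate 1 or 2, 0 neutrophil genes passed (limma).

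Genes of innate lymphoid cells were poorly covered. Of the 20 members of the list for innate lymphoid cell type 3 and type 17 lymphocytes, 5 passed the filter on low values. Among these, 0 passed the test (limma). An unadjusted p under 0.05 was found for 1 of them, Id2, and for 5457 of all 13956 fitted genes. The list's median was 0.03 (camera adjusted p = 0.783). Id2 differed by -0.20, Ahr by -0.11, Thy1 by 0.06 and Tnfsf11 by 0.05. The T and B lymphocyte list, with 5 fitted members, had a median of -0.08 (camera adjusted p = 0.639); H2-Aa differed by -0.37, H2-Ab1 by -0.31, Cd79b by 0.12 and Cd3e by -0.08.

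Several genes of the cell death machinery rose. Of 22 fitted members 5 rose and 0 fell (5 rose and 1 fell when adjusted over the list alone), and the list's median was 0.11 (camera adjusted p = 0.0166; adjusted p = 0.676 with an estimated correlation). Zbp1, a nucleic acid sensor that engages Ripk3, rose 2.32-fold (9.18 ± 0.40 to 10.40 ± 0.27, adjusted p = 0.0328). Ripk3, the kinase that phosphorylates Mlkl in necroptosis, rose 2.22-fold (9.30 ± 0.01 to 10.45 ± 0.15, adjusted p = 0.0122), and Birc3, which encodes the ubiquitin ligase cIAP2, rose 1.98-fold (adjusted p = 0.0197). Mlkl read 8.86 ± 0.12 and 9.44 ± 0.36 (adjusted p = 0.0896). The other members that rose were Casp8 (by 0.37) and Tradd (by 0.37), chosen after their values were seen. The list's shift was not called without CFLARs Tg replicate 1 (median 0.05, adjusted p = 0.23), its median was 0.19 without replicate 2, and 0 members passed without wild-type replicate 1 or 2.

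Stress and repair programmes moved up. Of 15 immediate early and heat shock genes 9 rose and 0 fell (13 when adjusted over the list alone), with a median of 0.45 (camera adjusted p = 2.13e-06; adjusted p = 0.376 with an estimated correlation); Egr1 rose by 1.29, Nr4a1 by 0.97, Ier3 by 0.95 and Hsph1 by 0.74. Of 12 epithelial repair genes 8 rose and 0 fell (9 when adjusted over the list alone), with a median of 0.77 (camera adjusted p = 3.60e-06; adjusted p = 0.405 with an estimated correlation). Sprr1a, a gene of the cornified envelope, rose from 8.11 ± 0.06 to 10.80 ± 0.04, and Tnip3, Ereg and Il1rn rose by 2.53, 1.54 and 1.53. Of 15 endoplasmic reticulum stress genes 7 rose and 1 fell (8 and 2 when adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0446; adjusted p = 0.676 with an estimated correlation). Atf3 rose by 1.66, Asns by 1.08 and the chaperone gene Hspa5 by 0.44, while Sesn2 fell by 0.60. That list's call was lost without wild-type replicate 1 (median 0.19, adjusted p = 0.0741), without CFLARs Tg replicate 1 (median 0.29, adjusted p = 0.183), after quantile normalization, median centring or ranking, with the lowest 50% of genes left out, and with sex type as a block (adjusted p from 0.0503 to 0.0703). Sprr1a passed without either wild-type array, Egr1 without wild-type replicate 2 only, and 0 other members of these lists passed without a wild-type array.

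Cell cycle genes lay higher in CFLARs Tg in 19 of 19 fitted members, of which 6 rose (7 when adjusted over the list alone), with a median of 0.37 (camera adjusted p = 9.59e-06; adjusted p = 0.676 with an estimated correlation). Rrm2, Mcm3, Top2a and Mcm5, which act in DNA synthesis, rose by 0.69, 0.57, 0.48 and 0.47. The call of Rrm2 was lost without a filter (adjusted p = 0.0557) and that of Top2a with the median of its probe sets. Without CFLARs Tg replicate 2 the list's median was 0.20. The intestinal stem cell list did not shift (14 fitted members, median -0.09, camera adjusted p = 0.743), and its members went both ways: 2 rose and 2 fell (3 and 3 when adjusted over the list alone). Cd44 rose by 0.85, the stem cell markers Lgr5 and Olfm4 fell by 0.44 and 0.43 (the call of Lgr5 was lost without a filter, adjusted p = 0.0536), and Prom1 differed by 0.54 (adjusted p = 0.0533). The other member that rose was Axin2 (by 0.30), chosen after its value was seen. None of these genes passed without wild-type replicate 1 or 2 (limma, 0 genes).

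Enterocyte programmes shifted down. Of 21 fitted enterocyte digestion and absorption genes 4 fell and 0 rose (4 when adjusted over the list alone), and 19 lay lower in CFLARs Tg, with a median of -0.52 (camera adjusted p = 0.000445; adjusted p = 0.676 with an estimated correlation). Without CFLARs Tg replicate 2 the median was -0.24. Slc2a2 fell by 2.78, the peptide transporter gene Slc15a1 by 1.09 and the fructose transporter gene Slc2a5 by 0.74. Fabp1 read 13.39 ± 0.02 in wild-type and 12.57 ± 0.69 in CFLARs Tg (adjusted p = 0.141). The other member that fell was Khk, the fructokinase gene, by 0.71, chosen after its value was seen, as were the maltase gene Mgam, with a difference of 0.01 (SE 0.05), and the brush border gene Vil1, with -0.08 (SE 0.09). All 14 fitted suckling-stage enterocyte genes lay lower, of which 3 fell (12 when adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.000419; adjusted p = 0.676 with an estimated correlation). Lactase (Lct) read 13.29 ± 0.04 and 11.80 ± 1.09 (adjusted p = 0.103), and Nox4, Ctsl and Cubn differed by -1.04, -0.90 and -0.82, and these 4 genes passed with sex type as a block (adjusted p from 0.0214 to 0.0410). The list's median was -0.39 without CFLARs Tg replicate 2. The members that fell were Otc, Neu1 and Dab2, by 0.82, 0.65 and 0.60, chosen after their values were seen. None of these genes passed without wild-type replicate 1 or 2 (limma, 0 genes).

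Genes of fatty acid oxidation under PPAR alpha fell: 6 of 13 fitted members fell and 0 rose (9 when adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.000703; adjusted p = 0.676 with an estimated correlation). The median was -0.27 without CFLARs Tg replicate 2. Pdk4 fell from 9.97 ± 0.27 to 8.49 ± 0.21, and Acot1, Ehhadh and Acaa2 fell by 1.27, 1.17 and 0.98. The call of Acaa2 (adjusted p = 0.0481) was lost after quantile normalization or median centring and without a filter (adjusted p = 0.0554, 0.0525 and 0.0536). Ileal bile acid genes went both ways: among 7 fitted members the nuclear receptor genes Nr0b2 and Nr1h4 fell by 1.99 and 0.64, the ileal bile acid transporter gene Slc10a2 rose by 0.91, and the list did not shift (median -0.19, camera adjusted p = 0.702; 1 rose and 2 fell when adjusted over the list alone). Fabp6 differed by 0.90 (SE 0.46). These 9 calls were lost without either wild-type array.

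Of the secretory lists, those of goblet and Paneth cells shifted up, and 1 gene of each was called without a block. Goblet cell genes had a median of 0.49 (camera adjusted p = 0.00921; adjusted p = 0.676 with an estimated correlation), and 1 of 12 fitted members rose, Spdef, the transcription factor gene of this lineage, by 0.45 (1 when adjusted over the list alone; chosen after its value was seen). The wild-type arrays themselves differed by a median of 0.49 over this list (XY minus XX), and without wild-type replicate 1 its median was 0.31. Zg16 read 9.89 and 11.19 in the wild-type XX and XY arrays and 11.50 and 12.10 in the XCFX and XCFY arrays, and Clca1, Spink4 and Tff3 differed between the genotypes by 1.05, 0.65 and 0.62. Paneth cell genes had a median of 0.98 (camera adjusted p = 0.0118; adjusted p = 0.676 with an estimated correlation), and 1 of 5 fitted members rose (3 when adjusted over the list alone), Nupr1, by 0.75, a stress-response gene that is not specific to Paneth cells and was chosen after its value was seen. The protease gene Mmp7, the defensin gene Defa24, the lysozyme gene Lyz1 and Ang4 differed by 1.62, 1.35, 0.98 and 0.87, with adjusted p from 0.0526 to 0.237. The list's median was 1.52 without CFLARs Tg replicate 1 and 0.61 without replicate 2. With sex type as a block, Zg16, Clca1, Spink4, Tff3, Mmp7, Defa24, Lyz1 and Ang4 passed (adjusted p from 0.00231 to 0.0457). Spdef and Nupr1 did not pass without wild-type replicate 1 or 2. The enteroendocrine list did not shift (16 fitted members, median 0.06, camera adjusted p = 0.783); somatostatin (Sst) fell by 0.60 and ghrelin (Ghrl) by 0.38 (2 fell when adjusted over the list alone), and Tac1 and Gip differed by 0.74 and -0.66. The tuft cell list had a median of -0.01 (10 fitted members, camera adjusted p = 0.923); Hpgds fell by 0.63 (1 fell when adjusted over the list alone) and Alox5ap, Alox5 and Trpm5 differed by 1.24, 0.35 and -0.18. The calls of Sst, Ghrl and Hpgds were also lost without either wild-type array.

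Lists for stroma and nerves did not pass the camera test. Endothelial genes had a median of -0.10 (12 fitted members, camera adjusted p = 0.0725), and Emcn, Kdr and Tek fell by 0.36, 0.30 and 0.29 (3 fell when adjusted over the list alone), while Plvap differed by -0.23. This list's shift passed without CFLARs Tg replicate 2 (median -0.19, adjusted p = 0.0128) and without a filter (median -0.10, adjusted p = 0.0353), and without CFLARs Tg replicate 1 its median was -0.05 (adjusted p = 0.493). Smooth muscle genes had a median of 0.09 (12 members, camera adjusted p = 0.216), with Des at 0.36, Tagln at 0.25, Synm at 0.21 and Mylk at -0.19. Limma called 0 of them. An unadjusted p under 0.05 was found for 3 of the 12, a smaller share than among all fitted genes (5457 of 13956). Fibroblast and matrix genes had a median of 0.01 (16 members, camera adjusted p = 0.783); Tnc rose by 0.66 and Fbln1 fell by 0.24 (0 when adjusted over the list alone), and Fn1 and Postn differed by 0.24 and -0.16. Enteric neuron and glia genes had a median of 0.00 (10 members, camera adjusted p = 0.783), with Ret at -0.36, Stmn2 at -0.10, Uchl1 at -0.06 and Tubb3 at 0.04. Of the erythroid list only Alas2 (0.17) and Slc4a1 (-0.12) were fitted, and the list was not tested. The calls of Emcn, Kdr, Tek, Tnc and Fbln1 were lost without either wild-type array, and all but that of Emcn also without a filter (adjusted p from 0.0507 to 0.0579).

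Lists for neighbouring organs gave mixed results. Colon genes had a median of 0.67 (9 fitted members, camera adjusted p = 0.0664), and 2 rose (3 when adjusted over the list alone): the carbonic anhydrase gene Car4, from 7.51 ± 0.00 to 9.70 ± 0.01, and B3galt5, by 1.86. Car1 differed by 1.24 and Mettl7b by -1.12. The colon list's shift passed without wild-type replicate 2 (median 0.88, adjusted p = 0.00743), with sex type as a block (0.0300) and without a filter (0.0473); Car4 passed without either wild-type array and B3galt5 without replicate 2 only. The list's median was 0.36 without wild-type replicate 1 (adjusted p = 0.127) and, with the lowest 50% of genes left out, -0.02 (adjusted p = 0.713). Stomach genes had a median of 0.11 (3 fitted members, camera adjusted p = 0.231), with Ctse at 0.50, Gkn1 at 0.11 and Tff1 at 0.06. Liver genes shifted down with a median of -1.11 (10 fitted members, camera adjusted p = 0.0189; adjusted p = 0.676 with an estimated correlation), and 3 fell (1 rose and 4 fell when adjusted over the list alone). Afp, a fetal serum protein gene, fell from 12.30 ± 0.05 to 10.54 ± 0.31; the others, Ambp and Ttr, fell by 0.91 and 0.84 and were chosen after their values were seen, and all 3 calls were lost without either wild-type array. Of the 10 liver genes 9 were lowest in the XCFY array, and the list's median was -1.77 without CFLARs Tg replicate 1 and -0.57 without replicate 2. Albumin (Alb) read 11.47 and 12.72 in the wild-type XX and XY arrays, 11.20 in the XCFX array and 6.57 in the XCFY array, and Ahsg followed the same order; Tat differed by 1.36 (adjusted p = 0.0514). Pancreas genes did not shift (9 fitted members, median -0.75, camera adjusted p = 0.23), and stood higher in the wild-type XY array than in the other 3: Ctrb1 read 10.16, 12.44, 9.67 and 7.70 in the XX, XY, XCFX and XCFY arrays, and Pnliprp1 read 6.72, 10.39, 6.84 and 6.18. Cpb1 and Cpa1 differed between the genotypes by -1.38 and -1.15. Without wild-type replicate 1 the pancreas list had a median of -1.60, and without wild-type replicate 2, the XY array, its median was -0.01.

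Interferon-response genes had a median of 0.15 and did not shift as a list (18 fitted members, camera adjusted p = 0.0762). Cxcl9 rose by 3.68 (SE 0.18) and Gbp3 by 1.14 (SE 0.16), and these were also the 2 that rose when adjusted over the list alone. Rsad2 and Mx1 differed by 1.06 (SE 0.46) and 0.80 (SE 0.33). The list's median was 0.33 without wild-type replicate 2, 0.47 without CFLARs Tg replicate 2 and -0.06 without CFLARs Tg replicate 1. When a wild-type array was left out, Cxcl9 still passed in both cases and Gbp3 in neither.

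In the XY-type pair, which compares 1 CFLARs Tg array with 1 wild-type array, 221 genes were at least 2-fold higher and 313 at least 2-fold lower in XCFY than in XY. The largest differences upward were Reg3g (5.53), Reg3b (5.05), Cxcl2 (4.80), Saa3 (4.61), H2-M2 (4.54) and Pla2g4c (4.26), followed by Gsdmc2 (3.84), Gsdmc4 (3.77), the cystatin gene Stfa2 (3.74) and Cxcl9 (3.68). The largest downward were Alb (-6.15), Mme (-4.92), Ctrb1 (-4.74), Ahsg (-4.37), G6pc (-4.36), Pnliprp1 (-4.22), Sectm1b (-3.84), Abcb11 (-3.82), Pck1 (-3.77) and Slc2a2 (-3.38). Of these, Alb, Ahsg, Ctrb1 and Pnliprp1 are liver and pancreas genes. The XCFY readings of Alb, Ahsg, Pnliprp1 and Abcb11 and the XY readings of Cxcl2, H2-M2, Gsdmc4 and Stfa2 lay within the range of background, so their differences are lower bounds in size and their order is uncertain. Antimicrobial genes (median 1.72), cytokine genes (1.53) and neutrophil genes (1.99) were among the lists above all 10000 matched random lists. Enterocyte (-0.73), suckling-stage (-0.88), liver (-1.78) and pancreas genes (-1.75) lay below all of them. Such places also occurred within a genotype. Goblet genes (0.49) and antimicrobial genes (0.18) lay above all random lists in wild-type XY minus XX. Enterocyte genes (-0.44) lay below all in XCFY minus XCFX. A place beyond the random lists therefore does not by itself mark an effect of the genotype.

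In the XX-type pair, 147 genes were at least 2-fold higher and 85 at least 2-fold lower in XCFX than in XX. The largest differences upward were Reg3g (5.66), Reg3b (5.21), H2-M2 (4.30), Pla2g4c (4.19) and Saa3 (3.98), with Cxcl2 between the last of these, followed by Cxcl9 (3.68), Nos2 (3.47), Duox2 (3.30) and Gsdmc2 (3.17). Since the wild-type means of H2-M2 and Cxcl2 lay within the range of background, their differences are lower bounds and their order is uncertain. The largest downward were Pck1 (-2.88), Abcb11 (-2.55), Cym (-2.50), Lrat (-2.43), Mme (-2.43), Sectm1b (-2.34), Slc2a2 (-2.17), G6pc (-2.12), Sdr16c5 (-1.88) and Smcp (-1.83). Antimicrobial genes had a median of 1.17, cytokine genes 1.43, neutrophil genes 1.03 and interferon-response genes 0.61. These were among the lists above all 10000 matched random lists, and suckling-stage genes (-0.42) lay below all of them. As in the XY-type pair, this does not by itself mark an effect of the genotype.

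The pairs differed in the same direction for most genes with large differences. Across genes, which are not independent replicates, the differences of the pairs correlated with a Pearson r of 0.827 and a Spearman rho of 0.768. At least 2-fold differences in both pairs were found for 192 genes, and 0 of the genes with such differences in both pairs went in opposite directions. Where the pairs differed by at least 1 on the log2 scale, the XY-type pair lay farther from 0 in 81 genes and the XX-type pair in 17. Cytokine genes had nearly equal medians (1.53 in the XY-type and 1.43 in the XX-type pair), while enterocyte genes had medians of -0.73 and -0.23 and neutrophil genes 1.99 and 1.03. The difference between the pairs was not tested, since it rests on 1 array of each kind.

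**Figure D3:**
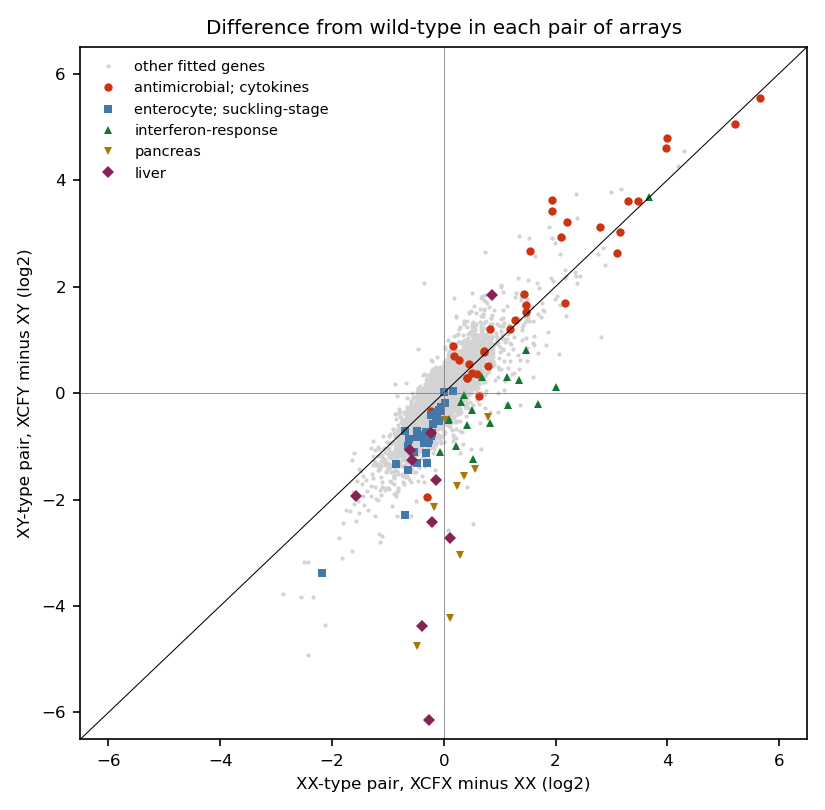
Difference from wild-type (log2) of each fitted gene in the XX-type pair (horizontal axis) and the XY-type pair (vertical axis), with gene lists marked by colour and shape and a line where both are equal. Antimicrobial and cytokine genes lay near the line up to Reg3g (5.66 and 5.53), enterocyte genes mostly below it, and pancreas genes spread downward in the XY-type pair alone, to -4.74 for Ctrb1.

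**Figure D4:**
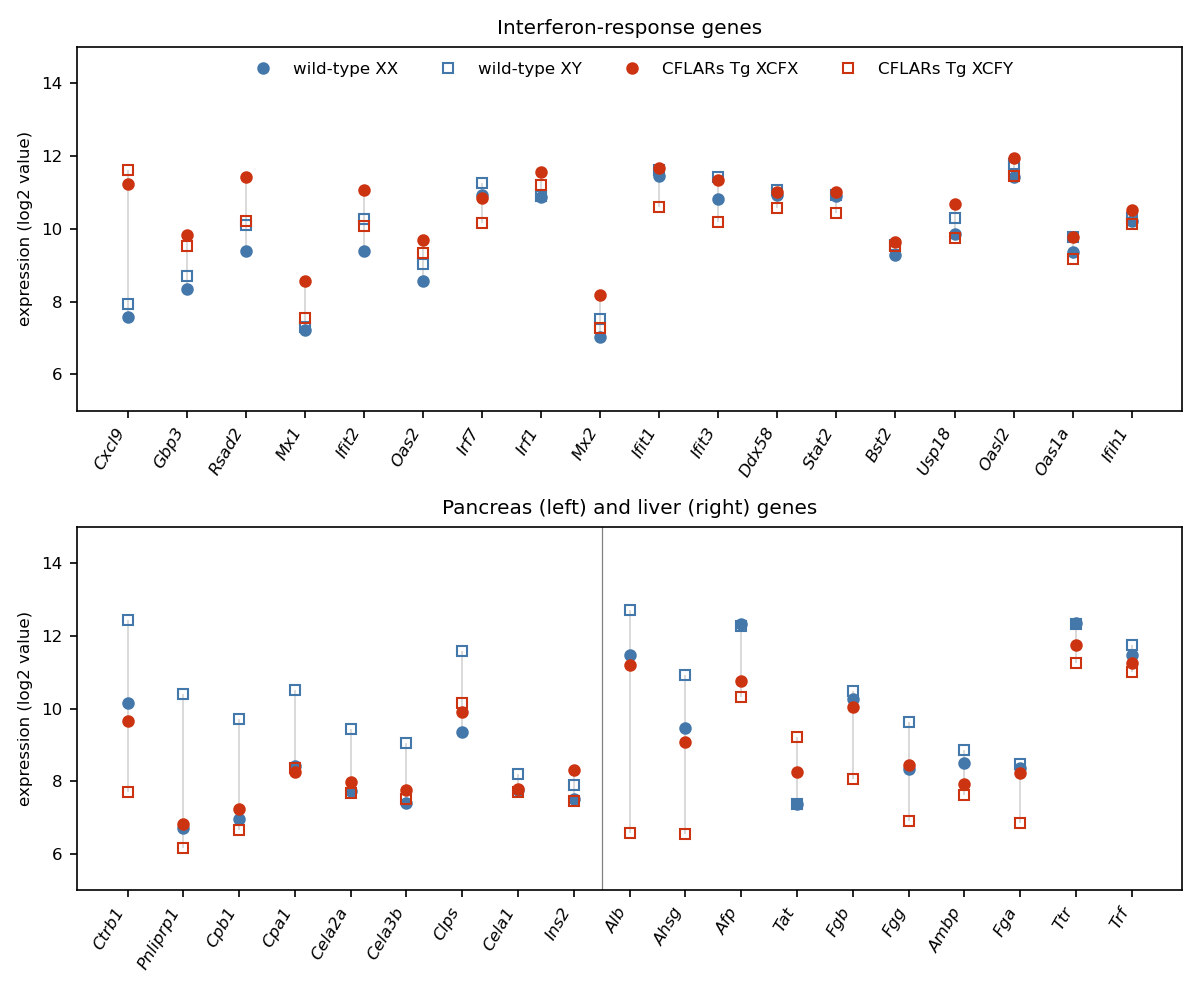
Expression (log2 value, vertical axis) on each of the 4 arrays of the fitted interferon-response genes (upper panel) and of pancreas and liver genes (lower panel), with points for arrays and grey lines for their range. Ctrb1 was highest in the wild-type XY array (12.44), and Alb was lowest in the XCFY array (6.57).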

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

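The gene lists were fixed before the data were examined, and all of the tests in this part were chosen after the results were seen. The genes named in this part outside the rule, such as Clps and Try5, were chosen after their values were seen. Differences between the pairs are given as the XY-type pair's value minus that of the XX-type pair and were not tested, since each pair holds 1 array per genotype.

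The pair medians had opposite signs for 6 of the 29 lists tested. The difference was -1.99 for pancreas genes, -0.83 for interferon-response genes, -0.72 for ileal bile acid genes, 0.11 for fibroblast and matrix genes, 0.0723 for enteric neuron and glia genes, and 0.0698 for the innate lymphoid cell list. Among the genes that the rule for named genes selects, those with opposite signs were the pancreas genes Pnliprp1 (-4.33) and Cpb1 (-3.33), the erythroid genes Slc4a1 (-0.83) and Alas2 (-0.39), the stomach gene Tff1 (-0.29), the neural genes Uchl1 (0.27) and Tubb3 (0.12), and Thy1 (0.31). Outside the wild-type XY array the readings of Pnliprp1 lay within or just above the range of background, so its sign in the XX-type pair is uncertain. Among probe sets with several or no gene symbols, which entered no comparison, 21 passed the same test between the genotypes (17 higher and 4 lower in CFLARs Tg, of 4947 fitted), 14 of them with several symbols.

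Pancreas genes stood higher in the wild-type XY array than in the wild-type XX array in 9 of 9 members, with a median of 2.09, above the matched random lists, 95% of which lay between -0.08 and 0.07. Ctrb1 read 12.44 and Clps 11.58 in that array, and 5 of the 9 genes lay above the filter value in all 4 arrays. A candidate explanation is pancreas tissue carried over into the wild-type XY sample, although the dissection is not described in the sources used here. It was tested on 11 fitted pancreas genes outside the list: 9 were higher in the wild-type XY array, with a median of 0.19, above the range of 95% of matched random lists (-0.06 to 0.07). Try5 and Rnase1 were higher by 2.62 and 1.25, and Ctrc and Tmed6 lower by 0.04 and 0.14. These genes mark the same tissue as the list, so any cause that raised the list could raise them too. The result goes with carried-over tissue but does not tell it apart from other causes. An effect of the genotype or of sex type would move the list alike in both pairs or both genotypes. The pair medians differed by 1.99 (95% bootstrap interval over genes 0.86 to 4.25) and the medians of the sex types by 2.38 (interval 1.24 to 3.33). These differences restate the pattern and hold no spread between samples, so genotype and sex type stay open.

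Interferon-response genes lay higher in XCFX than in XX in 17 of 18 members and higher in XCFY than in XY in 6 of 18. The baseline was higher in the wild-type XY array, where 18 of 18 members lay above the wild-type XX array. In these arrays the list also stood lower in XCFY than in XCFX (median -0.59, 95% bootstrap interval over genes -0.97 to -0.38). That difference is itself part of the pattern, compares 1 array with 1 array and holds no spread between samples. Whether a higher baseline alone is the cause therefore stays open. The median difference of the pairs over the list was -0.93, while 95% of matched random lists lay between -0.09 and 0.10. A scaling shared by genes of like expression would not set the list apart in this way. The list was picked for this difference, so nothing further follows from it. The value was -0.95 after quantile normalization and -0.95 after median centring, which act on all genes alike and could hardly change it. Between the sex types the list's median was 0.36 in wild-type and -0.59 in CFLARs Tg (difference 0.95, interval over genes 0.66 to 1.37), which restates the pattern and holds no spread between samples. Sex type, the location and copy number of the transgene, which the labels do not give, and differences between single mice stay open.

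The XCFY array lay farther from wild-type than the XCFX array in enterocyte genes. A difference in gain of the array would give all lists the same slope of the XY-type on the XX-type pair differences. This slope was 1.86 in the enterocyte lists and 1.09 in the antimicrobial and cytokine lists (difference 0.77, 95% bootstrap interval 0.53 to 1.38). The enterocyte lists were picked for their difference between the pairs, and the interval over genes holds no spread between samples. Of all called genes, 71.2% of the rises and 65.5% of the falls were larger in the XY-type pair, so gain stays open. The enterocyte list differed by -0.44 between XCFY and XCFX and by -0.00389 between the wild-type arrays (difference 0.43, interval over genes 0.24 to 0.57), which holds no spread between samples and leaves sex type open. A more distal stretch of intestine in the XCFY sample cannot be decided: the ileal bile acid list, itself made of enterocyte genes, moved by -0.0900 relative to the enterocyte list (interval -0.65 to 0.32), and colon genes were higher in XCFY by 0.27 (interval -0.05 to 0.63). A lower share of enterocytes in the XCFY sample cannot be told apart from lower expression per cell: smooth muscle, fibroblast and endothelial lists stood higher in XCFY by 0.09, 0.14 and 0.12 and the neuron list by 0.01, and the largest difference among them (0.13, interval -0.03 to 0.27 adjusted for 6 differences) included 0. The location and copy number of the transgene, which the labels do not give, and the severity of disease in single mice stay open and untested.

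The genotype split called 2695 genes, and the highest of the other 2 splits of the 4 arrays called 3. Of the 3 splits only 1 reached the real count, and 3 splits are too few for a share under 0.05.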

How the results depend on the processing

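Calls of single genes depended on the wild-type arrays, calls of lists on the assumed correlation. When an array was left out, its lone partner was assumed to vary like the other genotype. List tests of these fits used the preset correlation of 0.01. Estimated over all 4 arrays, the correlation was 0.89 in cell cycle, 0.74 in enterocyte and 0.98 in suckling-stage genes. A list called without an array therefore does not show that its shift holds across mice. Leaving out each array in turn gave 40 to 6559 genes, 34 to 3112 rises and 3 to 3447 falls, lowest without a wild-type array, since the spread then comes from the CFLARs Tg arrays, which differed more. Requiring a log2 difference of 0.5 left 63 genes (53 rises, 10 falls). Quantile normalization, median centring, other filters, the median of probe sets, all probe sets, a variance trend and sex type as a block gave 2292 to 3112 genes. With an estimated correlation 0 lists passed instead of 15; with the preset, 13 to 17 did. The titles share no replicate numbers, so the arrays were paired by sex type only: as a block it called 3112 genes, with 1 residual degree of freedom. Beyond the genes given beside their lists, it gained the calls of Car1, Mettl7b, Tac1, Gip, Fabp6, Prom1, Tat, Ctse and Alox5ap and lost those of Tek and Fbln1 among the named genes. Leaving out the lowest 50% of genes reduced the genes that differ by at least 1 between the pairs from 98 to 64, since fewer genes were counted (chosen after seeing the data); the pair counts stayed within 1.5 times. The offsets were not run. Low genes lie near background, which limits small differences.

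The lists and genes whose direction turned had not passed the test, and the cause was not tested. Leaving out each array in turn gave medians of -0.0390 to 0.00960 for enteric neuron, 0.0214 to 0.0648 for enteroendocrine, -0.0408 to 0.0750 for fibroblast, -0.732 to 0.176 for ileal bile acid, -0.0599 to 0.468 for interferon-response, -0.128 to -0.0190 for stem cell, -1.60 to -0.00543 for pancreas and -0.0183 to -0.00158 for tuft cell genes. With the lowest 50% left out the medians were 0.0172 for enteroendocrine and -0.0298 for stem cell genes, and without a filter 0.0226 for innate lymphoid genes. Where the median kept its sign, the direction of the camera test turned. Single genes ran from -0.145 to 0.0218 (Uchl1), -0.0337 to 0.120 (Tubb3), -0.409 to 0.177 (Slc4a1, also 0.00583 without CFLARs Tg replicate 2), -0.0478 to 0.172 (Thy1) and -0.0685 to 0.195 (Tff1). Among the other values of named genes, 1216 kept direction and side of the threshold, 166 lost the call and 93 gained it.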

Other observations

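Further gene families were found by a scan over symbol stems with at least 4 fitted members, chosen after the main results were seen: 33 of 653 families shifted (camera, preset correlation, adjusted p under 0.05), and 0 did with an estimated correlation. Related genes can share probe sequence, so members of a family are not independent. Several of these families act in protein turnover, protein folding and ribosome assembly, a grouping that was not tested. The families named here are a choice from the 33. Nup, Krt and Zfp, outside this grouping, had smaller p-values (camera) than most of those named. Nup rose in 6 of 19 members (median 0.32) and Krt in 7 of 20 (0.21), while Zfp fell in 41 of 279 and rose in 4 (-0.11). Most calls of single family members cannot hold without a wild-type array, where few genes passed at all. Of 7 alpha subunits of the proteasome (Psma) 5 rose, with a median of 0.46 (camera adjusted p = 0.00349; adjusted p = 0.988 with an estimated correlation), and of 14 regulatory subunits (Psmd) 9 rose, with a median of 0.37. Of 7 subunits of the chaperonin that folds actin and tubulin (Cct) 5 rose, with a median of 0.47. Of 8 nucleolar protein genes (Nop) 7 rose, Nop56 by 0.86, and 1 fell, Nop53, by 0.28, and 5 of 7 ribosomal RNA processing genes (Rrp) rose, with a median of 0.60. The mitochondrial folate enzyme gene Mthfd2 rose from 8.89 ± 0.09 to 9.89 ± 0.16.

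Guanylate-binding protein genes, which interferon-gamma induces, rose in 6 of 8 fitted members, with a median of 1.16 (camera adjusted p = 7.95e-05; adjusted p = 0.988 with an estimated correlation). Gbp5 rose from 6.98 ± 0.05 to 9.28 ± 0.10 and Gbp4 from 8.28 ± 0.04 to 10.45 ± 0.04, and the family's medians were 1.02 in the XY-type and 1.31 in the XX-type pair. Schlafen genes rose in 6 of 7 members, Slfn4 by 2.78. Among families that shifted down, 3 of 6 UDP-glucuronosyltransferase genes (Ugt) and 4 of 7 glutathione S-transferase mu genes (Gstm) fell, with medians of -0.74 and -0.57; Ugt2a3 fell by 1.36 and Gstm7 by 0.82. These enzymes conjugate lipids and foreign compounds. Aldehyde dehydrogenase genes fell in 6 of 18 members and peroxin genes (Pex), needed to form peroxisomes, in 4 of 13.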
